A study of Mus musculus with 15 samples.

How the data were processed

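Chromatin accessibility was measured by ATAC-seq, in which Tn5 transposase cuts and tags open DNA, in alveolar macrophages sorted from mouse lung. The labels describe the cells as CD45-positive, Ly6G-negative, SiglecF-positive and CD11c-positive. CGD (chronic granulomatous disease) mice are Cybb knockouts per the labels; Cybb encodes the membrane subunit of the phagocyte NADPH oxidase. The 15 samples form 5 groups of 3 samples: CD11b-low cells of WT mice at 4 and 12 weeks, CD11b-low cells of CGD mice at 4 and 12 weeks, and CD11b-high cells of CGD mice at 12 weeks. The labels carry no replicate number, so the samples of a group were numbered in accession order only.

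The files used here are 5 peak lists, 1 per group, in a layout of 10 columns. Bowtie2 and MACS2 are named without versions in the submitters' processing notes, which name the builds mm10 and hg19. The cells are from mouse, so mm10 is used throughout. The largest peak end on chromosome 1 was 195176946, which alone does not tell the builds apart. In each list, between 36.1% and 37.8% of the 20000 strongest regions had their midpoint within 1 kb of an annotated gene end, against 6.52% to 6.68% after a shift of 100 kb. How the 3 samples of a group were combined, whether peaks were called on pooled reads, and how Tn5 cut positions were shifted are not given in the sources used here. The deposited fold is the authors' ratio of signal to local background at each peak. The deposited −log10 p and −log10 q are the authors' values from peak calling, and they grow with sequencing depth. The summit offset in bases is a further deposited value, and it entered no result. The lowest deposited −log10 p was 2.00 in the WT list at 4 weeks, while the 1st percentile of region values lay at 16.2 there. All of these are the authors' own values per peak, used only to describe, rank or filter peaks within a list, and ranks from lists of different lengths show no change.

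Peaks of a list that overlapped or touched were merged into regions, and a region took the highest −log10 p and fold of its peaks. The 20000 regions of highest −log10 p in a list are called strong. A strong region that shared not even 1 bp with any peak of another list is called one-list-only. The term describes the deposited lists, which may have been filtered, and does not show closed chromatin. Counts have exact Clopper-Pearson 95% intervals of their share of 20000, which cover counting error only. With 1 list per group there is no replicate check, no test across samples and no p-value, and samples could not be left out in turn. Read depth per sample is unknown.

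A region was assigned to the gene body that held its midpoint (the gene with the nearer end where several did), and otherwise to the nearest protein-coding gene body within 50 kb. The plan had named the nearest transcription start site. The annotation used (GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes) came without strand, so start sites could not be told from gene ends. Of the 64706 regions in the union of the lists, 59188 were assigned to 15036 genes. No genome sequence was used here, so the planned search for sequence motifs was not run.

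For each of 29 gene lists, the genes with a one-list-only region were counted in each direction and set against 10000 random lists matched on the number of union regions per gene. A percentile was placed midway between the share of random lists with fewer hits and the share with no more hits. A list stood apart at the 99th percentile or above. Of 415 listed genes, 414 were protein-coding in the annotation. The named genes of each of the 5 main comparisons and each direction are the 10 with the strongest one-list-only region, plus up to 4 members of any list that stood apart and of the alveolar macrophage, monocyte and NADPH oxidase lists. Cybb and Itgam (CD11b) were looked up in every list first. These rules, lists and thresholds were fixed before the data were examined. A gene named outside the rule is said to have been chosen after its values were seen, and 1 gene that the rule names is not reported here.

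On simulated lists made from each comparison's first list by removing 200 strong regions, all 200 were found, and 0 were called when nothing was removed. This checks the counting alone, since each pair was otherwise the same list. Over 15036 genes, 0.400% of 1000 null gene lists reached the threshold, as did 100% of lists of 15 genes with 6 planted members. A measure added later was the difference between a pair of lists in strong regions per gene list. It compares ranks from lists of different lengths and was dropped, so its percentiles are not given.

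Alternatives tried were a −log10 q of at least 5, equal list lengths, 10000 strong regions or all regions, ranking by fold, at least 50% of a region covered, a gap of 500 bp, autosomes only, a gene distance of 10 kb, all genes within 50 kb, and other matching of random lists. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.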

Results

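Accessible chromatin of alveolar macrophages was compared between WT and CGD mice, between 4 and 12 weeks of age, and between CD11b-low and CD11b-high cells of CGD mice. Alveolar macrophages are the resident phagocytes of the airspaces, and CD11b is an integrin subunit that is usually low on them in the undisturbed lung. Each of the 5 groups of 3 samples is represented by 1 peak list. The WT lists held 68813 peaks at 4 weeks and 71298 at 12 weeks. The CGD CD11b-low lists held 86359 and 78700 peaks at these ages, and the CGD CD11b-high list held 89083. After merging, the lists held 41225, 44198, 48733, 48878 and 53952 regions in that order, covering 25.4, 26.1, 31.4, 28.9 and 32.4 Mb. The difference in list length accompanies every comparison between genotypes, and read depth is unknown.

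Cybb, the gene disrupted in this CGD model, lay in accessible chromatin in every list. Within 5 kb of the gene (chromosome X, 9435252 to 9487766, mm10) the WT lists held 4 and 7 regions at 4 and 12 weeks, and the CGD lists held 5, 4 and 6 regions. The strongest of these, near 9460382, ranked between 9864 and 12182 in the 5 lists. Peaks at a gene do not show whether it carries a disruption, so these values do not check the genotype labels. Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491), had 7 or 8 regions within 5 kb in each list. Its strongest region in the CD11b-high list (128121383 to 128122285) was also the strongest in CGD CD11b-low cells at 12 weeks (128121396 to 128122276). This region lies beyond the gene body. In the other 3 lists the strongest started near 128063245, within the gene body, and whether they held the first region is not given here.

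With every list cut to the length of the shortest, overlap was measured as the ratio of shared bases to bases in either list. The CD11b-high list had its lowest ratios with the WT lists, at 0.661 and 0.668, and a ratio of 0.682 with CGD CD11b-low at 4 weeks. Its highest ratio, 0.727, was with CGD CD11b-low cells of the same age. The genotypes had a ratio of 0.730 at each age, and the ages had 0.709 in WT and 0.726 in CGD.

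**Figure D1:**
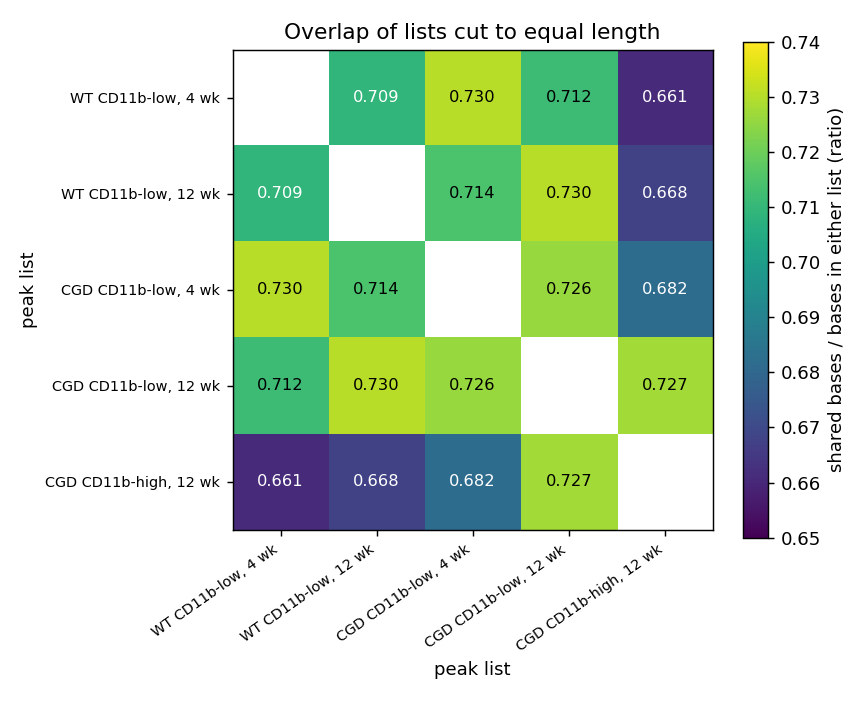
Ratio of shared bases to bases in either list for each pair of the 5 peak lists, each cut to its 41225 strongest regions; both axes name the list and the colour gives the ratio. The CD11b-high list has its lowest ratios with the WT lists (0.661 and 0.668) and its highest with CGD CD11b-low at 12 weeks (0.727).

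The comparison of genotypes at 4 weeks asked where chromatin of CD11b-low cells differed before the later age. CGD cells held 36 strong regions with no peak in the WT list (0.180% of 20000, interval 0.126 to 0.249%), and WT cells held 9 with no peak in the CGD list (0.0450%, 0.0206 to 0.0854%). The strongest CGD region lay 20.4 kb from Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29070084 to 29071146, −log10 p 425). The next lay in Ppm1h, a protein phosphatase, at H3c13, a histone gene, in Rbpj, the transcription factor of Notch signalling, and in Gse1. Regions near 2510039O18Rik, Mab21l3, Socs6, a suppressor of cytokine signalling, and Tle3, a corepressor, and in Tns1, an adhesion adaptor, completed the 10.

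In WT cells the 9 regions lay in or near Elovl5, an elongase of polyunsaturated fatty acids (chromosome 9, 77959714 to 77960174, −log10 p 192), Dgkd, Mcf2l, Nrp2, Srrm3, Psmg3, Cdc42bpb, H13 and Rap1a. Neutrophil markers were the list that stood apart in this comparison, through 1 of 11 genes: a region 3.44 kb from Mpo, the myeloperoxidase of neutrophil granules, gave percentile 99.2. The percentile was 96.1 with all genes within 50 kb, 86.6 with all regions at equal length and 49.8 with 10000 strong regions. No alveolar macrophage, monocyte or NADPH oxidase gene had a one-list-only region in either direction. Of the 36 CGD regions, 32 were present in the WT list at 12 weeks, and 30 were present in all 3 remaining lists, so most were missing from the 4-week WT list and present in the other WT list. The Ppm1h and Tns1 regions were in neither WT list.

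The same comparison at 12 weeks gave 60 strong CGD regions with no WT peak (0.300%, 0.229 to 0.386%) and 20 strong WT regions with no CGD peak (0.100%, 0.0611 to 0.154%). Ppm1h had the strongest CGD region (chromosome 10, 122885949 to 122886430, −log10 p 217). It was followed by Tpcn2, a channel of endolysosomes, Tns1, Arhgap31, Sh3pxd2b, an adaptor of podosomes, Disp1, Ankrd13a, Lrrc27, Map2 and Klf6, a zinc finger transcription factor of macrophages. The Klf6 region lay 24.0 kb from the gene. All 60 were present in the CD11b-high list, as were all but 14 of the 20000 strong regions of this CGD list. In the WT list at 4 weeks, 39 of the 60 were present.

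WT cells at 12 weeks held a very strong region in Hps6, a gene of lysosome-related organelle biogenesis (chromosome 19, 46003280 to 46003725, −log10 p 473, rank 1554), where the CGD CD11b-low list of that age had none. The other 3 lists held it. Atxn2, Smug1, Acsf2, Tnfrsf13b, Zfp654, Bcar3, BC016579, Scmh1 and Ggnbp1 followed. Klf6 was the listed gene among the CGD regions, and macrophage transcription factors were at percentile 80.6. No list stood apart, and no alveolar macrophage, monocyte or NADPH oxidase gene was among the one-list-only regions.

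Across both ages, 2411 of 64706 union regions were present in both CGD CD11b-low lists and neither WT list, and 393 showed the reverse. Independent differences at the 2 ages would give 1554 and 192, or 2421 and 343 when counted within 20 bins of region strength, and the observed numbers were 0.996 and 1.15 times the latter. Among union regions strong in at least 1 list, 96 were in both CGD CD11b-low lists and neither WT list, and 3 showed the reverse. Within bins of strength, independent differences would give 13.6 and 0.608. The 96 lay near Camk2d, Klf6, Tns1 and Myom3 among others. These genes were chosen after their values were seen, by the highest −log10 p in any list. All 96 were also in the CD11b-high list, whose strong regions counted here, as was 1 of the 3. Among regions strong in at least 1 CD11b-low list, the numbers were 15 and 2, against 1.43 and 0.376. Only the choice of regions changed here: the bins still used the highest −log10 p in any list, CD11b-high included. The opposite patterns, CGD-only at one age and WT-only at the other, held 7 and 30 regions strong in at least 1 list, against 1.85 and 3.25. They held 2 and 3 regions strong in at least 1 CD11b-low list, against 0.956 and 0.382 within the same kind of bins. The observed number was 9.22 times that of independence for the 30 and 7.05 times for the 96, so an excess was not particular to regions with the same genotype difference at both ages. Over all union regions the opposite patterns numbered 1220 and 651, 0.965 and 1.02 times the numbers of independence within bins.

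CD11b-high cells of CGD mice held 96 strong regions with no peak in CD11b-low cells of CGD mice of that age (0.480%, 0.389 to 0.586%), against 14 in the other direction (0.0700%, 0.0383 to 0.117%). Of the 96, 64 were present in none of the remaining lists, while 17 were in the WT list at 4 weeks, 20 in that at 12 weeks and 28 in the CGD list at 4 weeks. The other lists held far fewer strong regions of their own: 1 in WT at 12 weeks and 0 in each of the remaining 3. With all lists cut to 41225 regions the 64 became 114 and the other lists held 0 to 3. Over all regions of these cut lists the contrast was smaller. Of CD11b-high regions, 87.7% overlapped the CGD CD11b-low list of that age, and 88.0% of its regions overlapped the CD11b-high list. The CD11b-high list held 6.91% of its regions alone, and the other lists 1.91% to 4.61%. Regions held by CD11b-high cells alone lay in Plxdc1 (chromosome 11, 97971124 to 97971765, −log10 p 230), Zfp704 and Atg10, an autophagy gene, and 3.79 kb from Trem2, a lipid-sensing receptor of macrophages (chromosome 17, 48355685 to 48356450, −log10 p 175, fold 23.1). Trem2, named after its values were seen, had other regions near the gene in all 5 lists, the widest of them from 48346103 to 48347812 in WT at 4 weeks.

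The 10 strongest of the 96 further included Hps6 and Atxn2, which were missing from the CD11b-low list of that age alone, and Gm30733, Fam174a, Spef1l, Dlgap1 and Amz2. Among the strongest in the other direction was a region 37.5 kb from Ptger2, a prostaglandin E2 receptor (chromosome 14, 45040987 to 45041603, −log10 p 177). Cdh15, Haao, Rasd2, Sulf2, Clcn1, Thumpd2, Igsf9b and Gcnt2 followed, and 12 of the 14 regions were present in all 3 remaining lists. No gene list stood apart. Markers of interstitial or monocyte-derived macrophages lay at percentile 97.2 and lipid-associated macrophage genes at 91.2, both through Trem2 alone, and glycolysis and hypoxia genes at 90.3 through Pfkp. Alveolar macrophage, monocyte and NADPH oxidase lists had no one-list-only member.

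**Figure D2:**
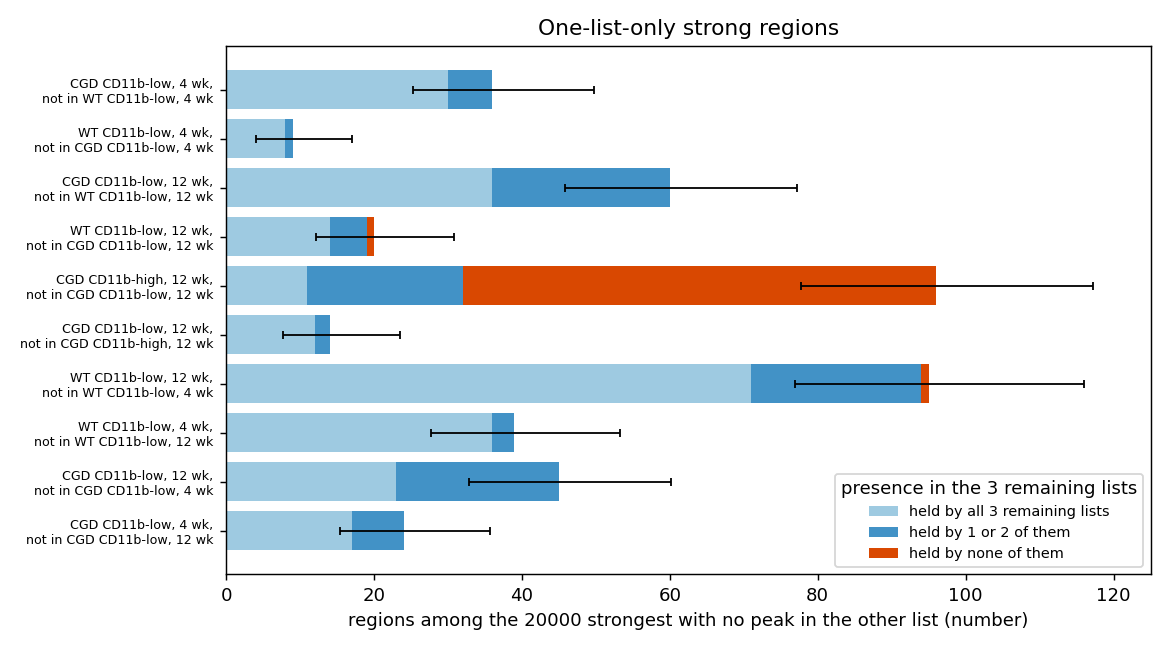
Number of regions among the 20000 strongest of the first list that share no base with a peak of the second, for the 10 directions of the main comparisons; colours give presence in the 3 remaining lists and error bars are exact 95% intervals. In CD11b-high cells 64 of 96 are in no other list, while the other directions hold at most 1 such region.

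Set against WT CD11b-low cells of the same age, CD11b-high cells of CGD mice held 521 strong regions with no WT peak (2.61%, 2.39 to 2.84%), and WT cells held 73 with no CD11b-high peak (0.365%, 0.286 to 0.459%). Genotype and CD11b level differ together here. Of the 521, 445 were present in CGD CD11b-low cells of that age, 242 in those at 4 weeks and 168 in WT cells at 4 weeks. Lipid-associated macrophage genes stood apart at percentile 99.7, with 4 of 14 genes: Gpnmb, a lysosomal glycoprotein (chromosome 6, 49027967 to 49028462, −log10 p 178), Trem2, Cd63, a tetraspanin of late endosomes, and Mmp12, the macrophage elastase. The Cd63 and Mmp12 regions were also in CGD CD11b-low cells at 12 weeks, the Gpnmb region in those of both ages, and the Trem2 region in no other list. Monocyte genes lay at percentile 83.1 through S100a4. The percentile of lipid-associated genes was 98.0 with random lists matched on strong regions and 44.1 with 10000 strong regions.

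**Figure D3:**
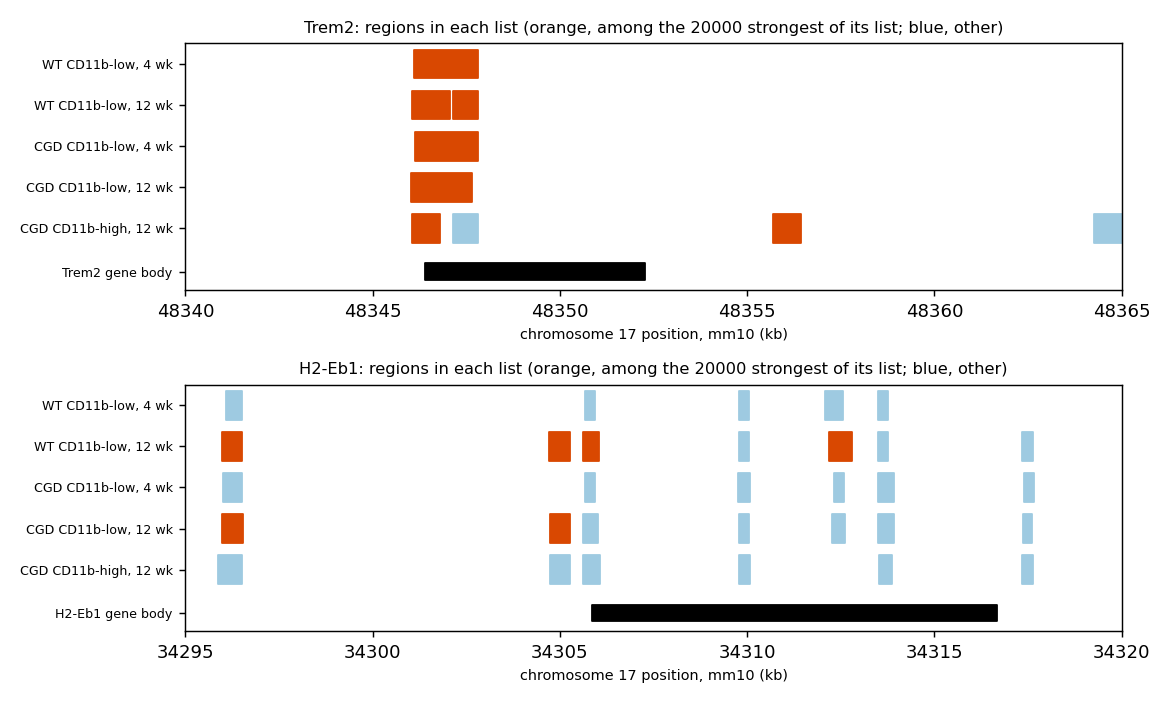
Regions of each peak list around Trem2 and H2-Eb1 on chromosome 17 (position in kb, mm10), 1 row per list; orange regions are among the 20000 strongest of their list, blue ones are not, and black bars are gene bodies. Only the CD11b-high list has the region from 48355685 to 48356450, and neither 4-week list has the region that starts at 34304716 in WT at 12 weeks.

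Age was compared within each genotype. In WT, 95 strong regions at 12 weeks had no peak at 4 weeks (0.475%, 0.384 to 0.580%), and 39 strong regions at 4 weeks had none at 12 weeks (0.195%, 0.139 to 0.266%). This order depended on the setting: it turned to 157 against 160 when at least 50% of a region had to be covered and to 5565 against 5847 with all regions at equal length. The strongest at 12 weeks lay near Cdkn1a (−log10 p 274) and Krt42, followed by H3c13, Ttll7, Ndrg1, a gene of stress and hypoxia responses, 2310061N02Rik, Olfr877, Chsy1, Sap30bp and Gse1. Of the 95, 71 were present in all 3 remaining lists, among them the Cdkn1a, H3c13 and Gse1 regions. At 4 weeks Igf2bp3, an RNA-binding protein typical of fetal cells, had the strongest region (chromosome 6, 49208399 to 49209304, −log10 p 231), followed by Pdzd2, Myo10, Arhgef37, Med27, Jmjd1c, Ppm1n, Tmem249, Hcfc1 and Src. All 39 were present in both CGD CD11b-low lists. H2-Eb1 was the listed gene with a region at 12 weeks, and antigen presentation was at percentile 95.7. With all genes within 50 kb it was at percentile 100, through Cd80 and the neighbouring H2-Aa, H2-Ab1 and H2-Eb1. That setting credits a region to every gene near it, so the H2 genes can share a region and need not be separate hits. Random lists draw genes singly, so this percentile is no stronger support.

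In CGD, 45 strong regions at 12 weeks had no peak at 4 weeks (0.225%, 0.164 to 0.301%), and 24 showed the reverse (0.120%, 0.0769 to 0.178%). The order turned to 69 against 200 with the 50% rule, to 7008 against 7581 with all regions and to 4480 against 4963 with all regions at equal length. Elovl5 led at 12 weeks (−log10 p 296), with Defb34, Lrrc27, Ap3s2, Srd5a2, Dync1i2, Adgb, Krt42, H2-Eb1 and Zdhhc18. H2-Eb1 encodes a chain of MHC class II, and its region (chromosome 17, 34304742 to 34305281, −log10 p 127) lay 0.855 kb from the gene body. It was present in the WT list at 12 weeks and the CD11b-high list, and in neither list at 4 weeks. Antigen presentation lay at percentile 98.1 through H2-Eb1, and interferon response genes at 98.2 through Oas1a. With all genes within 50 kb antigen presentation was at percentile 100, through H2-Eb1 and its neighbours H2-Aa and H2-Ab1. As in WT, these neighbours can share a region and need not be separate hits, so this percentile is no stronger support. At 4 weeks Hps6 led (−log10 p 626), followed by Stat2, a transducer of interferon signals, Nedd4l, Atxn2, Tsku, Hip1r, Hopx, Bcar3, Sash1 and Col23a1.

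Lung epithelial markers lay at the threshold, percentile 99, at 4 weeks in CGD through Hopx alone, 1 of 10 genes, with a region 40.7 kb from the gene. An exact calculation gave 98.99, below the threshold. Interferon response genes lay at 98.9 through Stat2, and past the threshold with a gene distance of 10 kb (99.2) and with random lists matched on strong regions (99.3). Regions at the Y-linked genes Eif2s3y, Uty and Ddx3y, chosen after their values were seen, numbered 4 in WT and 3 in CGD at 4 weeks and 0 in each 12-week list, beside both age comparisons; a further Y region, near Gm52481, was in all 5 lists, and the labels give no sex. The counts depend on the number of strong regions: with 10000 of them, none of the 10 main counts exceeded 7. Over all 12 directions, 348 percentiles were computed and 3 reached the threshold, beside 3.48 at a rate of 1%. That rate is no upper limit, since ties with random lists are counted in part and a single hit can pass more often. No listed gene of 14 of the 29 lists had a one-list-only region in any direction.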

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

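Both tests given here, of turnover and of the X chromosome, were chosen after the Y-linked regions had been seen.

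Regions at the Y-linked genes Eif2s3y, Uty and Ddx3y lie outside the comparisons of the report and appeared in lists of 1 age. The WT list at 4 weeks held 4 (Eif2s3y, 2 at Uty, and Ddx3y) and the CGD list at 4 weeks held 3 (Eif2s3y and 2 at Uty), with −log10 p between 31.9 and 89.1. The 3 lists at 12 weeks held 0 at these genes, although the WT list at 4 weeks is the shortest of all. A Y region near Gm52481 was in all 5 lists and was left out of these numbers. Its −log10 p was 41.3 in WT and 114 in CGD at 4 weeks. In the 12-week lists of WT, CGD CD11b-low and CD11b-high cells it was 93.2, 119 and 117. This region thus did not follow the regions at Eif2s3y, Uty and Ddx3y across the ages. Its presence at 12 weeks goes against a lack of the Y chromosome there unless its reads also match another chromosome, which was not tested. Ordinary turnover between lists is argued against: of 15727 autosomal regions of the same strength held by both 4-week lists, 106 (0.674%) were missing from all 12-week lists. A difference in sex between the ages is a candidate explanation that stays open, since the labels give no sex. The share of regions on the X chromosome in WT was 1.76% (1.64 to 1.90%) at 4 weeks and 1.88% (1.75 to 2.01%) at 12 weeks. This share counts called regions and not copies of the chromosome, so it cannot decide for or against a difference in sex. Xist, on the X chromosome, held 1 region in WT and 2 in CGD at 4 weeks, and 2 or 3 in the 12-week lists.

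Some strong regions were CGD-only at one age and WT-only at the other, a difference between the ages that was not tested. These were 7 regions that were CGD-only at 4 weeks and WT-only at 12 weeks, and 30 with the reverse. Independent differences within bins of strength would give 1.85 and 3.25. Among regions strong in a CD11b-low list they were 2 and 3, against 0.956 and 0.382, where the bins still drew on all lists, CD11b-high included. Over all union regions the observed numbers were 0.965 and 1.02 times the numbers of independence.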

How the results depend on the processing

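The 3 equal-length settings that use the shortest of all 5 lists and the exact percentile were chosen after seeing the data. So was the choice of regions strong in a CD11b-low list. Counts are given in the order CGD without WT and WT without CGD at 4 weeks, the same pair at 12 weeks, CD11b-high without CD11b-low and the reverse, 12 without 4 weeks and the reverse in WT, the same pair in CGD, then CD11b-high without WT and the reverse. A −log10 q of at least 5, a gap of 500 bp and autosomes alone left all 12 counts within 1.5 times their main values.

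With 10000 strong regions the counts were 1, 1, 4, 2, 7, 1, 2, 2, 1, 1, 72 and 2, so that the 4-week genotype pair and both age pairs were level, and 0 gene lists stood apart. With all merged regions they were 10935, 2869, 9665, 4619, 10896, 5686, 7733, 5154, 7008, 7581, 14952 and 4737. Ranking by fold gave 779, 143, 760, 238, 897, 297, 755, 414, 534, 370, 1926 and 366. Requiring at least 50% of a region to be covered gave 246, 22, 169, 60, 221, 73, 157, 160, 69 and 200, and 119 for WT without CD11b-high. These settings count more or fewer regions by construction; what else moved the counts was not tested. In CGD the age pair turned its order with all regions and with the 50% rule, as the WT age pair did with the 50% rule, and the cause was not tested.

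Cutting each pair to equal length moved only WT without CD11b-high, to 110. It changes nothing where the list without the region was already the shorter one, so it is no test of depth for CGD without WT. Cutting all 5 lists moved CD11b-high without CD11b-low to 150, the reverse to 29, CGD at 12 without 4 weeks to 68 and WT without CD11b-high to 166, as shortening the list searched must add regions. All regions at equal length gave 5120, 4542, 5042, 4744, 5059, 4943, 5565, 5847, 4480, 4963, 6964 and 6571; against the whole other list they gave 5120, 2869, 4443, 3014, 3436, 2171, 5565, 5154, 2963, 3148, 6319 and 3306. With both lists cut, both age pairs turned their order and the genotype pairs lay closer together in the same order; against the whole list the CGD age pair alone turned. The cause was not tested.

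With all genes within 50 kb, 5 percentiles reached the threshold, and the cause was not tested. They belong to antigen presentation, in 3 directions, and to lipid-associated macrophage genes. Antigen presentation passed through the neighbouring H2-Aa, H2-Ab1 and H2-Eb1, which share regions, with Cd80 besides for WT at 12 against 4 weeks. Interferon response genes passed at 4 weeks in CGD with 10 kb (99.2) and with matching on strong regions (99.3). With all 5 lists cut, antigen presentation passed in WT against CD11b-high cells (99.65). With all regions at equal length, T and NK cell genes passed for CGD at 4 weeks against WT (99.3), lipid handling for CD11b-low against CD11b-high cells (99.1) and neutrophil genes for CGD at 4 against 12 weeks (99.45). Against the whole list, T and NK cell genes (99.3), neutrophil genes (99.4) and control genes of other organs, for CD11b-high cells against WT (99.1), passed. Regions in both CGD lists and neither WT list numbered 96 among regions strong in any list and 15 among those strong in a CD11b-low list. The reverse numbered 3 and 2, as fewer regions entered. The motif search and its 2 alternatives were not run. With 1 list per group, no sample could be left out. No paired analysis was possible because the labels carry no replicate number and each group has 1 list. Read depth per sample is unknown and limits every count.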

Other observations

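All tests in this part and the age overlap were chosen after the values they concern had been seen.

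Antigen presentation genes, among them those of MHC class II, all had a region in every list, 12 of 12. With all lists cut to equal length they held 34 regions in WT at 4 weeks and 37 at 12 weeks. CGD CD11b-low cells held 38 and 36 at these ages, and CD11b-high cells held 36. In the same order, 11, 23, 11, 16 and 11 of them were strong within their own list. H2-Aa, chosen after its values were seen, held 3 regions in each list. Of the 18 alveolar macrophage identity genes, 17 had a region in WT at 12 weeks and 18 in each other list. A comparison of strong regions between lists was dropped, as ranks from lists of different lengths show no change. Differences in the other counts were not tested.

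Some strong regions separated the ages in both genotypes. Of regions strong in a CD11b-low list, 25 were in both 12-week lists and neither 4-week list, against 1.58 from independent differences within bins of strength, and 2, at Tsku and Egfem1, showed the reverse, against 0.429. H2-Eb1, Defb34, Kcnn3, Ttll7, Ndrg1, Oas1f, Ecm1 and Mid1, which is on the X chromosome, were among the genes of the 25. Of the 25 regions, 24 were held by CD11b-high cells, the exception lying in Sap30bp. With strength from any list the numbers were 77 and 7, against 10.2 and 1.10. Over all union regions they were 1425 and 1111, against 1216 and 920. The opposite patterns, which join 12 weeks alone in one genotype to 4 weeks alone in the other, held 2 and 3 regions strong in a CD11b-low list, against 1.02 and 0.604, and 7 and 30 with strength from any list, against 2.11 and 6.03. Over all union regions they lay below independence of the age differences, at 1220 and 651 against 1401 and 801. They are the same regions as those with opposite genotype differences at the 2 ages, set here against independent age differences. Age and the presence of regions at Eif2s3y and Uty separate the lists alike.

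The 64 strong regions held by CD11b-high cells alone, near Trem2, Plxdc1, Zfp704 and Atg10 among others, were weighed against 3 explanations. List length alone is argued against, since CGD CD11b-low at 4 weeks, the list nearest in number of peaks, held 0 such regions, and with all lists cut to 41225 regions CD11b-high cells held 114 against 0 to 3 in each other list. Other cell types in the gate (neutrophils, eosinophils, dendritic, T, NK, B, epithelial, endothelial and stromal cells) would mostly be removed by the CD45, Ly6G, SiglecF and CD11c sort; 0 of the 64 regions lay at their 75 markers (upper limit 5.60%), too few to decide beside 0.160% of all strong CD11b-high regions. Interstitial or monocyte-derived macrophages in the gate stay open as a candidate source, although the SiglecF sort would remove most interstitial macrophages: 1 of the 64 lay at their 15 markers (1.56%, interval 0.0396 to 8.40%), beside 0.0850% of all strong CD11b-high regions, and its gene, Trem2, is also a lipid-associated macrophage gene. A state of alveolar macrophages that differs with CD11b level was not tested apart from these.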
